A study of Mus musculus with 9 samples.

How the data were processed

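Gene expression was measured on Affymetrix arrays in CD11b positive, Ly6G negative myeloid cells sorted into Ly6C high, medium and low gates, with 3 arrays per gate and 9 in total. RNA was amplified before hybridization. The values are log2 intensities deposited by the authors, background corrected, normalized between arrays and summarized per probe set by RMA according to the processing notes, whose version and settings are not stated. They were used as deposited, with no pseudocount and no further normalization. Per the labels, the cells of all gates were collected on the same day. Nothing in the labels says that the replicates of a gate are separate animals, so the p-values measure the spread between these samples, which may be technical. For arrays the depth is not a count, and the number of arrays limits the precision. The genome build is not given in the sources used here, and no coordinates are printed.

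Of 41345 probe sets, 23521 had exactly 1 gene symbol, 1814 had several and 16010 were not in the probe table; the last groups were left out. Gene identifiers of 23328 probe sets matched a RefSeq table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed. A gene was measured by its probe set with the highest mean over all arrays, which decided between probe sets for 1082 genes. The 22180 genes left were tested without a filter on dim genes.

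Comparisons used R 4.3.3 and limma 3.58.1 (lmFit and eBayes, two-sided moderated test) with all 9 arrays in a single fit, 6 residual degrees of freedom, and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The 3 pairwise comparisons were low versus high, medium versus high and low versus medium, beside a moderated F test over the 3 gates. Pairs of comparisons share the arrays of a gate, so their gene sets were not compared with each other. Gene lists, 31 in number, were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it, and fry compares a list with no other genes. The lists had 588 members, of which 540 were measured and 48 were not analysed here. Adjusted p-values of lists come from limma camera, and those of genes from limma. Adjusted over the list alone means the same limma p-values adjusted within that list. Genes with groups that do not overlap have every array of a gate above every array of the other.

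The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per comparison, the transcripts of the sorted proteins, the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those past the threshold with groups that do not overlap (5 and 5 for the comparisons with medium), up to 4 members with the largest difference past the threshold of each list, and a fixed set of genes given whatever their test. Predicted gene models were left out of the largest differences. For the position of Ly6C medium, the difference medium minus high was divided by low minus high for each gene.

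The alternatives included quantile normalization repeated on the genes tested, centring of each array and the mean of all probe sets of a gene. There were 2 filters on dim genes (above the array median, or a log2 value of at least 6, on at least 3 arrays). Further fits used a trended and robust prior, array weights, the replicate number as a fixed or random block, or only the 2 gates compared. An equal-variance test per gene without moderation over genes, a 2-fold threshold, and leaving out each array in turn were also used. Leaving out the genes that follow the fibroblast markers was added after the data were seen.

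The procedure was tested on simulated data with 200 changed genes per comparison among 22180 genes. For low versus high it recovered 73.1% of genes changed by a log2 value of 1, 95.5% at 2 and 100% at 3, with 4.28% of calls false. For medium versus high the shares were 70.1%, 88.1% and 98.5%, with 5.52% false. For low versus medium they were 67.2%, 97% and 98.5%, with 6.42% false. Of 31 unchanged simulated lists, 0 were called. The simulated genes varied independently, while estimated correlations within the real lists reached 0.503. The simulation therefore cannot show how often correlated lists are called in error.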

Results

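Gene expression was measured in myeloid cells of the wounded hindpaw of male C57BL/6J mice aged 8 weeks, 24 h after an incision. The cells carried CD11b, an integrin chain of myeloid cells, and lacked Ly6G, a surface protein of neutrophils. They were sorted by surface Ly6C, which is high on classical monocytes that have recently left the blood and low on many resident macrophages and dendritic cells. The 3 gates, Ly6C high, medium and low, had 3 arrays each, and the values of a gate are means of log2 intensity over its 3 arrays. The array medians lay between 3.93 and 4.10, and the number of arrays limits the precision. Across genes, which are not independent replicates, arrays of the same gate correlated at 0.983 to 0.989 and arrays of different gates at 0.964 to 0.989. The first principal component held 39.1% of the variance and ordered the gates, with scores of -32.6 to -25.0 in Ly6C high, -15.9 to -1.17 in medium and 27.0 to 41.7 in low.

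The transcripts of the sorted proteins were read first. Ly6c2, which encodes Ly6C, stood at 12.27 ± 0.20 (SD, n = 3) in Ly6C high, 11.22 ± 0.04 in medium and 8.33 ± 0.93 in low. It was 15.4-fold lower in low than in high (limma adjusted p = 0.00102) and 7.43-fold lower in low than in medium (adjusted p = 0.00895). Medium and high differed by a log2 value of -1.05, which was not past the threshold (limma adjusted p = 0.527). Their arrays did not overlap, at 12.08 to 12.48 in high and 11.20 to 11.27 in medium. The fit shares 1 spread over the gates, and low varied most, with replicate 3 at 9.40 against 7.69 and 7.90. Ly6c1 was near the floor of the array in every gate (2.97 ± 0.66, 2.75 ± 0.08 and 2.75 ± 0.04). Itgam, which encodes CD11b, was bright in all gates (11.02 ± 0.15, 10.90 ± 0.06 and 10.58 ± 0.13; adjusted p = 0.0579 for low versus high), and Ly6g was dim (3.02, 3.06 and 3.58; adjusted p = 0.591). Adgre1, which encodes a surface protein of mature macrophages, was at 9.84 ± 0.30, 10.10 ± 0.25 and 10.28 ± 0.26 (adjusted p = 0.276).

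Ly6C low cells differed from Ly6C high cells in genes of the classical monocyte list. Cd177, a surface glycoprotein counted in that list, fell from 8.89 ± 0.17 (SD, n = 3) in high to 4.49 ± 0.78 in low. This was a 21.1-fold difference (limma adjusted p = 0.000435). Chil3, a chitinase-like secreted protein of newly recruited monocytes, was 10.8-fold lower in low (limma adjusted p = 0.00344). Vcan, the proteoglycan versican, was 8-fold lower (limma adjusted p = 0.00485). Low replicate 3 stood nearest to high for Cd177 (5.37), Chil3 (9.16) and Vcan (8.23). The other low arrays reached at most 4.23, 7.53 and 7.31, while Ccr2 showed no such gap (9.29 on replicate 3 against 9.33 and 9.41). Ccr2, the receptor that draws monocytes out of the bone marrow, moved less, from 10.14 ± 0.07 to 9.35 ± 0.06 (1.73-fold lower, adjusted p = 0.00178). Of 15 measured classical monocyte genes, 11 were lower in low and 0 higher, and adjusted over the list alone 12 were lower and 1 higher. Ly6c2, the transcript of the sorted protein, is among the 11, so the sort itself set part of this result. The median log2 difference was -2.03 (limma camera adjusted p = 3.59e-17, and 0.00512 with an estimated correlation). The nonclassical monocyte list went both ways, with 4 of 15 genes higher and 5 lower (adjusted p = 0.101), and 5 higher and 8 lower adjusted over the list alone. Its members Ace, Apoc2 and Itgal were lower in low, whereas Itgax was higher. The values of Ace and Itgal follow those of the fibroblast markers over the arrays, gate differences included. Within Ly6C high, Itgal was highest on replicate 3 (8.2), where the fibroblast marker Col1a2 was lowest (9.4), while Ace was also lowest there (6.3). Cx3cr1, the fractalkine receptor, was higher by 1.02 (adjusted p = 0.0259), a call that was lost without 4 of the 9 arrays in turn (up to 0.0937 without low replicate 1). Nr4a1, which patrolling monocytes depend on, was at 9.81, 8.94 and 9.55 in high, medium and low (adjusted p = 0.681 for low versus high). Fibroblast markers were lower in low together with the monocyte genes, at a median log2 difference of -3.

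Genes of resident tissue macrophages rose in Ly6C low. Cd163, the scavenger receptor for haptoglobin bound to haemoglobin, stood at 6.17 ± 0.30 (SD, n = 3) in high, 8.10 ± 0.38 in medium and 10.21 ± 0.23 in low, 16.5-fold higher in low than in high (log2 difference 4.05, SE 0.22, adjusted p = 9.98e-05). Lyve1, a hyaluronan receptor, rose 19.4-fold from 6.99 ± 0.66 to 11.27 ± 0.15 (adjusted p = 0.00181). Vsig4, a complement receptor, rose 23.2-fold (adjusted p = 0.000105), and Timd4, a receptor for dying cells, 10.9-fold. Mrc1, the mannose receptor, was already bright in high (9.84 ± 0.12) and reached 11.13 ± 0.19 in low (2.45-fold, adjusted p = 0.000846). Among 26 tissue macrophage genes, 18 were higher and 1 was lower, Fcgr1, which was chosen after its values were seen; adjusted over the list alone the counts were 19 and 2. Their median log2 difference was 1.33 (adjusted p = 3.59e-17, but 0.118 with an estimated correlation). Of 30 genes for efferocytosis and lipid handling, 10 were higher, among them Mfge8, Stab1 and Timd4, and 3 were lower. Adjusted over the list alone 12 were higher and 9 lower, and the list was not called (median 0.0710, adjusted p = 0.111). The lysosome list was not called either (camera adjusted p = 0.812). Of its 25 genes, 2 were higher, Atp6v0d2 and Cd63, and 0 lower, with 3 and 1 adjusted over the list alone. The Cd63 call was lost without 5 of the 9 arrays in turn (up to 0.0864 without high replicate 3).

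Dendritic cell genes also rose in Ly6C low. Ccl17 and Ccl22, chemokines that attract T cells through CCR4, were 24.5-fold and 23.8-fold higher (adjusted p = 0.00262 and 0.00275). Ccr7, the receptor that guides dendritic cells to lymph nodes, stood at 6.41 ± 0.64 (SD, n = 3) in high, 6.72 ± 0.29 in medium and 9.48 ± 0.12 in low (8.37-fold, adjusted p = 0.000902). Cd207, which encodes the Langerhans cell lectin langerin, rose from 4.38 ± 0.30 to 7.22 ± 0.16 (7.19-fold, adjusted p = 0.000118). Flt3, the growth factor receptor of dendritic cells, rose 3.09-fold (adjusted p = 0.00198). In all, 9 of 23 dendritic cell genes were higher and 0 lower, and 14 were higher adjusted over the list alone (median 0.620, adjusted p = 2.19e-09, and 0.0071 with an estimated correlation). Of 13 genes for MHC class II presentation, 5 were higher and 0 lower, and 6 were higher adjusted over the list alone (median 0.411, adjusted p = 0.000494, and 0.0399 with an estimated correlation). The peptide loading gene H2-DMb2 rose 4.97-fold (adjusted p = 0.00262). H2-Aa rose 2.17-fold (adjusted p = 0.0200), a call lost without 2 of the 9 arrays in turn, low replicate 1 (0.073) among them. The natural killer cell receptor gene Klrd1 moved with these genes and was 8.87-fold higher in low (adjusted p = 0.00208).

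Genes of alternative activation, the macrophage state set by interleukin 4, rose as a list. Among its higher members, Ccl17 and Ccl22 are also dendritic cell genes and Mrc1 and Cd163 tissue macrophage genes in the lists used here. Alox15 is also an eosinophil marker there, so the list is not separate evidence from those lists. Mgl2, a lectin of dermal dendritic cells and macrophages, was 27.1-fold higher in low (adjusted p = 0.00208), and 11 of 19 genes were higher. Chil3 and Tgm2 of the same list were lower, and Tgm2 was chosen after its values were seen. The counts adjusted over the list alone were 12 and 2 (median 1.22, adjusted p = 9.1e-08, and 0.00919 with an estimated correlation). Retnla was 22.6-fold higher with an adjusted p of 0.0476, a call that was lost without 7 of the 9 arrays in turn (up to 0.157 without low replicate 2). Arg1, an arginase of the same state, was not past the threshold (10.22, 11.01 and 9.85 in high, medium and low; adjusted p = 0.521 for low versus high). Npl, a sialic acid lyase, stands outside the lists and had the largest rise among the named genes, 27.2-fold (5.48 in high and 10.25 in low, adjusted p = 0.00025).

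Interferon response genes were higher in Ly6C high. Oas3, a sensor of viral RNA, was lower in low by a log2 difference of -1.29 (adjusted p = 0.000374), as were Irf7 (-1.54, adjusted p = 0.00476) and Zbp1 (-1.54, adjusted p = 0.00223). Of 24 genes, 11 were lower and 0 higher, and 15 were lower adjusted over the list alone (median -0.829, adjusted p = 4.76e-15, and 0.0399 with an estimated correlation). Glycolysis and hypoxia genes were also lower in low, with Hif1a (-1.14, adjusted p = 0.0021), the glucose transporter gene Slc2a1 and the oxidase gene Ero1a past the threshold out of 22, and 9 adjusted over the list alone. Their list call (median -0.460, adjusted p = 6e-07) was lost at an adjusted p = 0.184 with an estimated correlation. For pattern recognition receptors, 5 of 27 genes were lower, including Trem1, Tlr9 and Clec4e, and only Mrc1 was higher. This became 16 lower and 2 higher adjusted over the list alone (median -0.427, adjusted p = 5.06e-07, but 0.0872 with an estimated correlation). The calls of those 3 receptors were each lost without at least 1 array (up to 0.11 for Trem1, 0.0604 for Tlr9 and 0.112 for Clec4e, all without low replicate 1). Fibroblast markers were lower in the same direction as these 3 lists (10 of 11).

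Single inflammatory cytokine genes were not past the threshold between low and high in the fit without a block. With the replicate number as a fixed block, Il1b and Ptgs2 passed (limma adjusted p = 0.0424 and 0.0108). The labels do not say that these numbers pair the samples. Il1b was at 12.15, 11.92 and 11.72 in high, medium and low (adjusted p = 0.219 for low versus high), and Tnf at 11.32, 11.63 and 11.54 (adjusted p = 0.826). Nos2 was at 5.88, 6.48 and 5.34 (adjusted p = 0.171), and Ptgs2, the inducible prostaglandin synthase, at 12, 11.91 and 11.04 (adjusted p = 0.0815). With limma, 0 of 19 cytokine genes passed over all genes and 0 adjusted over the list alone, against 6 lower at an unadjusted p under 0.05. The list as a whole was shifted lower in low (median -0.429, adjusted p = 0.000861), a call lost at an adjusted p = 0.451 with an estimated correlation. Il10 was at 9.94, 10.13 and 9.74 (adjusted p = 0.912), and of 16 anti-inflammatory mediators only Socs3 was past the threshold, lower in low. That list had 2 higher and 1 lower adjusted over the list alone and was not called (adjusted p = 0.128). Among 25 pain mediators, 3 were higher in low, Alox5, Alox15 and Cx3cr1, and 0 were lower. Adjusted over the list alone 4 were higher and 3 lower (adjusted p = 0.712). Alox5, the 5-lipoxygenase gene of leukotriene synthesis, rose 6.9-fold (adjusted p = 0.00534). The calls of Socs3 and Alox15 were each lost without 4 of the 9 arrays in turn (up to 0.0938 without low replicate 1 and 0.0734 without low replicate 2).

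Chemokines and their receptors went both ways. Of 25 chemokine genes, 6 were higher in low, among them Ccl17, Ccl22 and Ccl8, and 3 were lower, among them Cxcl12, which stromal cells make. There were 6 higher and 4 lower adjusted over the list alone (adjusted p = 0.812). Of 23 chemokine and adhesion receptors, 6 were higher, including Ccr7 and Itgax, and 6 lower, including Fpr2 and Itgal; 7 were higher and 9 lower adjusted over the list alone (adjusted p = 0.408). Matrix remodelling and growth factor genes split into 3 higher, including Igf1 and Timp2, and 4 lower, including Mmp8, of 22. There were 6 higher and 7 lower adjusted over the list alone (median -0.145, adjusted p = 0.266). The Igf1 call was lost without 3 of the 9 arrays in turn (up to 0.0827 without low replicate 1). Cell cycle genes rose in low, with Mcm3 (log2 difference 1.58, adjusted p = 0.0019) and Mcm6 (2.00, adjusted p = 0.0108), subunits of the replicative helicase, among 5 of 29 past the threshold and 0 lower. Adjusted over the list alone 15 were higher (median 0.609, adjusted p = 2.35e-10, but 0.0872 with an estimated correlation). The dissociation stress list, genes switched on while tissue is digested, was not called (Hspa1a and Egr1 higher and Ier3 lower of 19; 3 and 1 adjusted over the list alone; adjusted p = 0.704). The calls of Hspa1a and Egr1 were lost without at least 1 array (up to 0.0725 and 0.109, both without low replicate 1). That of Ier3 was lost without each of the 9 arrays in turn (up to 0.147 without low replicate 1).

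Markers of other cell types were read as measured facts. Fibroblast genes differed most: 10 of 11 were lower in low and 0 higher, both over all genes and adjusted over the list alone. Col1a2, a collagen chain, was 23.1-fold lower in low (adjusted p = 0.000428), and Dpt, Lum and Col3a1, also of the matrix, differed by -4.03, -3.92 and -3.43. The list median was -3 (adjusted p = 9.2e-19, and 0.0399 with an estimated correlation). Endothelial markers had a median of -0.353 with only Kdr of 10 past the threshold, 3 lower adjusted over the list alone (adjusted p = 0.000889, but 0.188 with an estimated correlation). The Kdr call was lost without 5 of the 9 arrays in turn (up to 0.105 without low replicate 2). Eosinophil markers were higher in low, with 3 of 8 higher, Prg2, Ccr3 and Alox15, and 0 lower, and 4 higher adjusted over the list alone. The list median was 0.335 (camera adjusted p = 0.00235, but 0.0872 with an estimated correlation), although Siglecf was dim (3.95, 4.05 and 4.38, limma adjusted p = 0.0966). The calls of Prg2 and Alox15 were each lost without 4 of the 9 arrays in turn (up to 0.0733 without high replicate 2 and 0.0734 without low replicate 2). That of Ccr3 was lost without 1 (0.06 without low replicate 1). Neutrophil markers were not called (1 of 18 higher, Retnlg, and 2 lower, Mmp8 and Csf3r; 2 and 2 adjusted over the list alone; adjusted p = 0.812), and S100a8 was at 7.47, 9.08 and 8.73 (adjusted p = 0.488). The Csf3r call was lost without 5 of the 9 arrays in turn (up to 0.0977 without low replicate 1). Of 10 natural killer cell markers, Klrd1 and Klrk1 were higher and 0 lower, also adjusted over the list alone (median -0.0392, adjusted p = 0.533), and Ncr1 was near the floor (3.06, 3.36 and 2.95; adjusted p = 0.82).

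Markers of the remaining cell types were not called. Mast cell and basophil markers had 1 of 12 higher, Kit, and 0 lower, also adjusted over the list alone (adjusted p = 0.0674). Keratinocyte markers had 1 of 13 higher, Sfn, and 0 lower (median -0.297, adjusted p = 0.217). Schwann cell markers had 1 of 6 higher, Pmp22, at 5.63-fold, and 0 lower (adjusted p = 0.373). In the T cell, B cell, skeletal muscle, and platelet and erythroid lists limma passed 0 genes in either direction, against 1 in each at an unadjusted p under 0.05 (list adjusted p = 0.971, 0.63, 0.704 and 0.889). For the chemokine, receptor, lysosome, dissociation stress, natural killer cell, T cell, and platelet and erythroid lists, the median, mean and test differed in sign.

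In total 1258 of 22180 genes differed between low and high, 744 higher in low and 514 lower (5.67%, against 3960 at an unadjusted p under 0.05). At 2-fold or more there were 598, of which 355 were higher and 243 lower. The share higher in low depended on scaling. It was 59.1% as deposited, 53.4% with quantile normalization repeated (670 higher and 584 lower) and 55.1% with arrays centred (691 and 562). All 1258 had groups that did not overlap, and over all genes 20.1% did not overlap, against 10% by chance. The count was 596 without low replicate 1, 649 without low replicate 2, 800 without high replicate 2 and 781 without high replicate 3. With the 2 gates fitted alone it was 644, and an equal-variance test per gene without moderation over genes passed 6. Of 79 named genes past the threshold, 55 kept their calls without each array in turn.

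**Figure D1:**
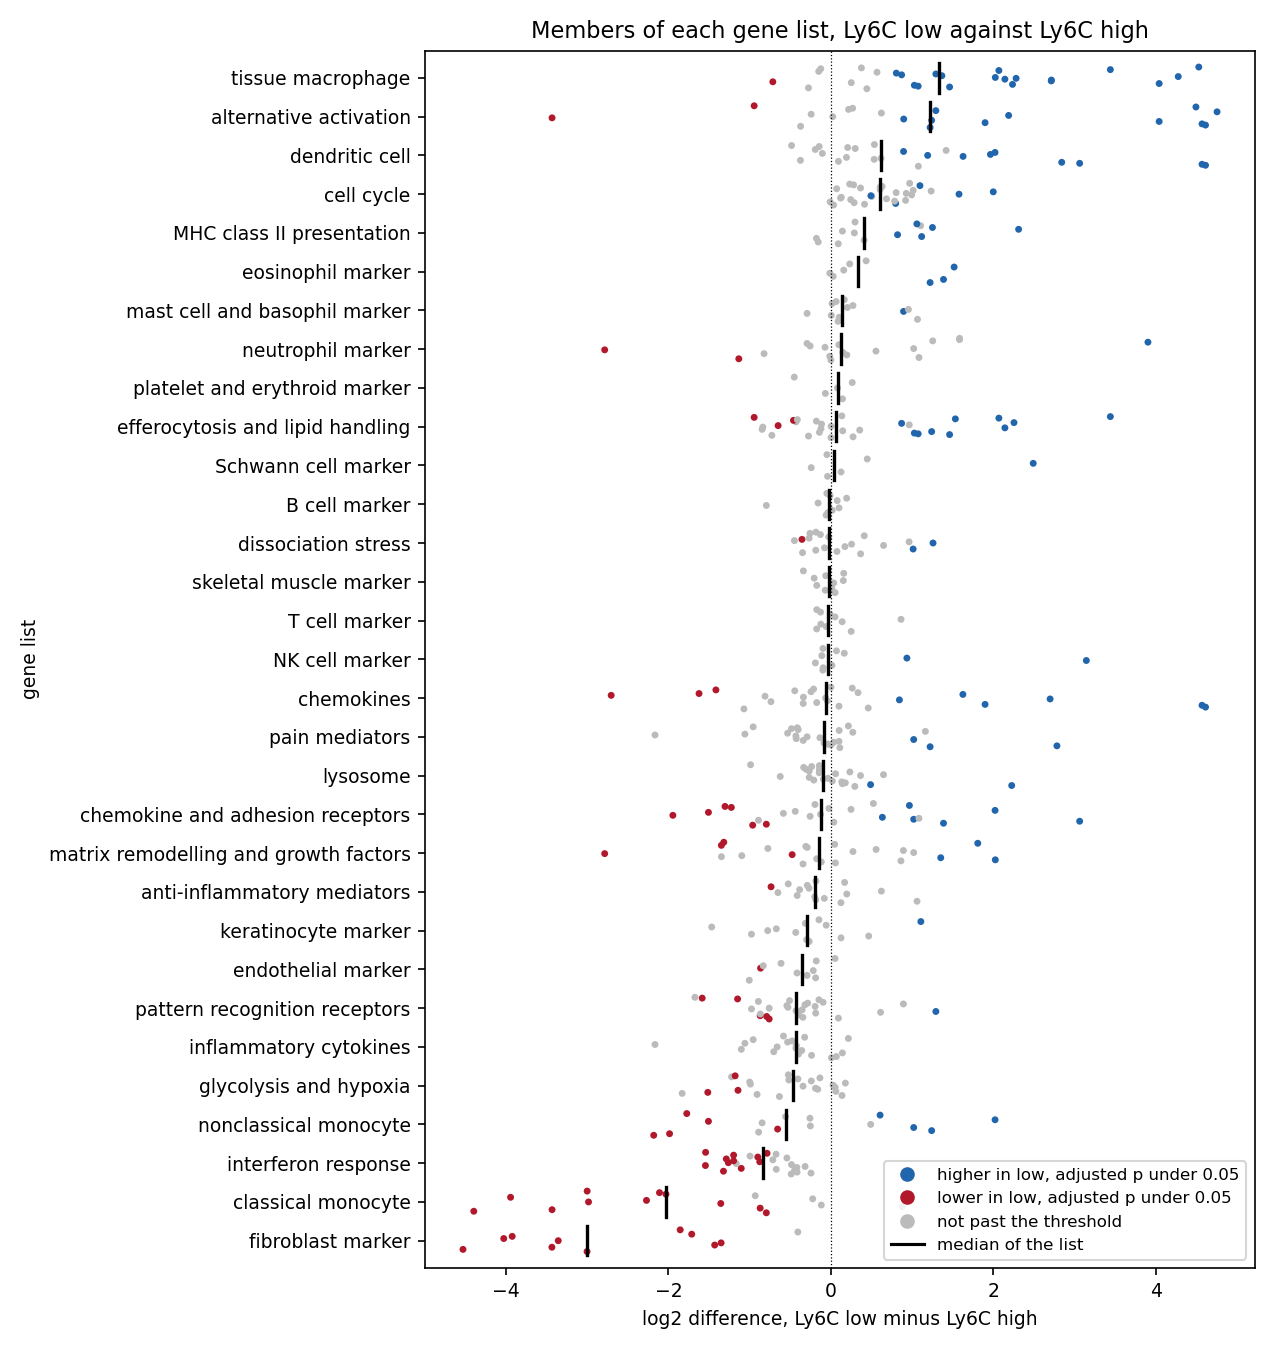
Log2 difference between Ly6C low and Ly6C high (x axis, positive when higher in low) for each measured member of the gene lists (y axis, sorted by median), 3 arrays per gate. Each point is a gene, coloured when past the threshold and grey when not, and the black bar is the list median, which ran from -3 for fibroblast markers to 1.33 for tissue macrophage genes.

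The comparison of Ly6C medium with Ly6C high asks what differs between sorted cells that carry less and more surface Ly6C. Few genes rose. Cd163 was 3.82-fold higher in medium (adjusted p = 0.0176), and Atp6v0d2, a subunit of the proton pump, went from 3.22 to 5.48 (4.79-fold, adjusted p = 0.0176). Cd36, a receptor for fatty acids, was 1.97-fold higher (adjusted p = 0.0404). Ly6a2, a gene of the Ly6 family, was the lowest against high, at 10.16 ± 0.32 (SD, n = 3) in high, 6.36 ± 0.39 in medium and 5.39 ± 0.40 in low, 14-fold lower in medium (adjusted p = 0.00145). Ly6a2, Ifitm6 and Cxcl12 are among the 127 genes whose values follow those of the fibroblast markers over the arrays, gate differences included. Within Ly6C high, Ly6a2 and Ifitm6 were highest on replicate 3 (10.4 and 10.3), where the fibroblast marker Col1a2 was lowest (9.4). Cxcl12 was also lowest on that array (8.7). Hp, which encodes haptoglobin, fell 2.46-fold (adjusted p = 0.0176), and Ifitm6, a membrane protein gene of monocytes, differed by -1.75 (adjusted p = 0.0215). Mrc1 (log2 difference 0.68, adjusted p = 0.0814) and Ccr2 (-0.34, adjusted p = 0.31) were not past the threshold. The fibroblast markers Col1a2 (8.03-fold, adjusted p = 0.021) and Lum (-3.31, adjusted p = 0.0215) and the chemokine Cxcl12 (6.69-fold, adjusted p = 0.0176) were also lower. Apart from Ly6a2, these calls were all lost without medium replicate 1, with adjusted p-values from 0.0968 for Cd163, Atp6v0d2 and Cxcl12 to 0.18 for Cd36, and the call of Cd36 was lost without each array in turn.

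By list, medium rose in tissue macrophage genes (2 of 26 higher and 0 lower; 10 higher adjusted over the list alone; median 0.511, adjusted p = 3.85e-10, but 0.332 with an estimated correlation). Alternative activation rose as well (2 of 19, Cd163 and Cd36; 6 adjusted over the list alone; median 0.680, adjusted p = 0.000278, and 0.0455 with an estimated correlation). Efferocytosis and lipid handling had 1 higher and 3 adjusted over the list alone (median 0.160, adjusted p = 5.67e-05, but 0.214 with an estimated correlation). The lysosome list had only Atp6v0d2 past the threshold (median 0.143, adjusted p = 0.00203, but 0.348 with an estimated correlation). Classical monocyte genes were lower, Hp and Ifitm6 over all genes and 9 adjusted over the list alone (median -0.690, adjusted p = 9.44e-11, and 0.0189 with an estimated correlation). Fibroblast markers moved with them, 8 of 11 lower and 10 adjusted over the list alone (median -2.36, adjusted p = 3.58e-29, and 0.041 with an estimated correlation). Endothelial markers were shifted lower with 0 genes past limma's threshold, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone (median -0.330, adjusted p = 0.000328, but 0.29 with an estimated correlation). Nonclassical monocyte genes had 1 higher, Cd36, and 1 lower, Itgal, with 1 and 4 adjusted over the list alone (median -0.124, adjusted p = 0.0102, but 0.214 with an estimated correlation).

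A further 4 lists were shifted lower in medium with 0 genes past limma's threshold, against 3, 5, 4 and 4 at an unadjusted p under 0.05. These were interferon response (median -0.177, adjusted p = 0.00114, but 0.364 with an estimated correlation), dissociation stress (-0.234, adjusted p = 0.000399, but 0.332), glycolysis and hypoxia (-0.0550, adjusted p = 0.0345, but 0.648) and pattern recognition receptors (-0.148, adjusted p = 0.0483, but 0.487), the last with 1 higher and the others with 0 adjusted over the list alone. Leaving out 1 array ended 5 of the 12 list calls. Without medium replicate 1 the nonclassical and interferon lists were at 0.143, and without high replicate 1 glycolysis was at 0.67 and dissociation stress at 0.0652. Without high replicate 3 pattern recognition receptors were at 0.573. Dendritic cell genes (adjusted p = 0.568) and MHC class II genes (adjusted p = 0.856) were not called. Median, mean and test differed in sign for the matrix remodelling, pain mediator and T cell lists.

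In total 53 genes differed between medium and high, 9 higher in medium and 44 lower, against 1671 at an unadjusted p under 0.05, and 45 differed by 2-fold or more. Over all genes 10.7% had groups that did not overlap, against 10% by chance. The count was 2 without medium replicate 1, 4 without medium replicate 2, 11 without medium replicate 3 and 12 without high replicate 2. It was 30, 20 and 31 without low replicates 1, 2 and 3, and Ly6a2 alone of 18 named genes past the threshold kept its call without each array in turn. With the 2 gates fitted alone it was 1, and an equal-variance test per gene without moderation over genes passed 0 (1126 unadjusted). Without the genes that follow the fibroblast markers, gate differences included, limma passed 0 (1554 unadjusted). Those genes hold 37 of the 44 lower genes. Ly6a2 is among the genes left out there, and the 9 higher and 7 lower genes that stayed in the test kept their log2 differences, with adjusted p-values of 0.0603 or more over fewer small p-values; Cd163 was at 1.94 (SE 0.22) before and after.

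**Figure D2:**
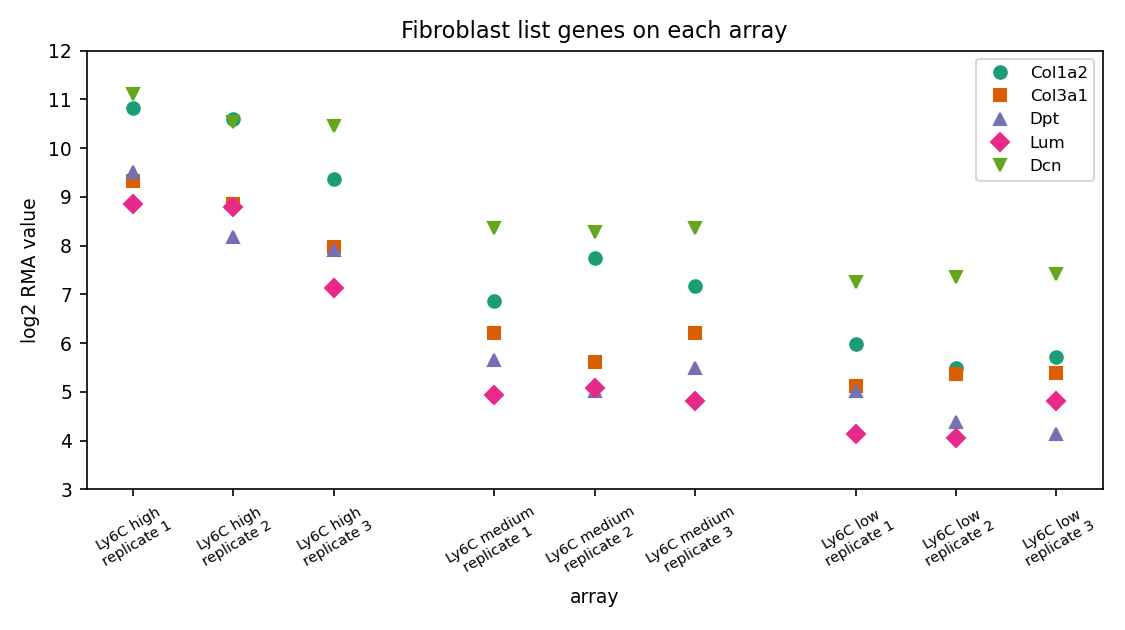
Log2 intensity (y axis) of the fibroblast marker genes Col1a2, Col3a1, Dpt, Lum and Dcn on each of the 9 arrays (x axis, grouped by gate). Each point is the value on an array, and Col1a2 lies at 9.37 to 10.83 on the Ly6C high arrays, 6.87 to 7.75 on medium and 5.50 to 5.99 on low.

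The comparison of Ly6C low with medium asks which genes separate the end of the Ly6C range from its middle. Aqp1, a water channel, had the largest rise, 14.5-fold in low (log2 difference 3.86, SE 0.19, adjusted p = 0.000169). Vsig4 was 9.74-fold higher (adjusted p = 0.00172), Ccr7 6.77-fold (adjusted p = 0.00414), Cd207 5.44-fold (adjusted p = 0.00134) and H2-DMb2 5.89-fold (adjusted p = 0.00499). Cd163 rose a further 4.32-fold (adjusted p = 0.00414). Of the genes lower in low, Hp fell 3.21-fold (adjusted p = 0.00245), Vegfa, a growth factor for vessels, 2.64-fold (adjusted p = 0.00414), and Hif1a differed by -1.11 (adjusted p = 0.00664). Oas3 was lower by a log2 difference of -0.87 (adjusted p = 0.00555). Chil3 (-2.74, adjusted p = 0.0217) and Cd177 (-2.39, adjusted p = 0.0166) were lower too, but without medium replicate 3 they were at 0.0929 and 0.0696. Nos2 was lower by -1.14 (adjusted p = 0.024), a call lost without 5 of the 9 arrays in turn (up to 0.0971 without low replicate 1), and Arg1 differed by -1.16 (adjusted p = 0.0524).

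By list, dendritic cell genes rose (9 of 23 higher and 0 lower; 13 higher and 1 lower adjusted over the list alone; median 0.801, adjusted p = 2.09e-10, and 0.00748 with an estimated correlation). Tissue macrophage genes rose (10 of 26; 16 higher and 2 lower adjusted over the list alone; median 0.891, adjusted p = 7.19e-12, but 0.243 with an estimated correlation). MHC class II had 1 higher, H2-DMb2, and 2 adjusted over the list alone (median 0.423, adjusted p = 8.04e-05, and 0.0306 with an estimated correlation). Alternative activation had 5 higher and 1 lower, with 10 and 3 adjusted over the list alone (median 0.615, adjusted p = 3.08e-05, and 0.0275 with an estimated correlation). Cell cycle had 1 higher, Mcm3, and 11 adjusted over the list alone (median 0.515, adjusted p = 2.27e-10, but 0.108 with an estimated correlation). Eosinophil markers had 0 past limma's threshold, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone (median 0.257, adjusted p = 0.00581, but 0.143 with an estimated correlation). The dissociation stress list was higher in low with only Egr1 past the threshold and 3 adjusted over the list alone (median 0.396, adjusted p = 0.000164, but 0.273 with an estimated correlation). Leaving out 1 array ended the calls of Egr1 (0.111 without low replicate 1) and Mcm3 (0.054 without medium replicate 3).

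Classical monocyte genes were lower in low than in medium, 7 of 15 over all genes and 10 adjusted over the list alone. Ly6c2, the transcript of the sorted protein, is among the 7. The list median was -0.842 (camera adjusted p = 7.19e-12, and 0.00748 with an estimated correlation). Interferon response genes were lower (4 of 24, Irf7, Zbp1, Oas3 and Mx1; 12 adjusted over the list alone; median -0.696, adjusted p = 7.19e-12, but 0.0769 with an estimated correlation). Glycolysis and hypoxia had 3 lower and 6 adjusted over the list alone (median -0.243, adjusted p = 0.000164, but 0.376 with an estimated correlation). Pattern recognition receptors had 1 higher, Mrc1, with 1 higher and 4 lower adjusted over the list alone (median -0.329, adjusted p = 0.000164, but 0.243 with an estimated correlation). Inflammatory cytokines had only Nos2 past the threshold (median -0.310, adjusted p = 0.00899, but 0.605 with an estimated correlation), and lysosome genes had 0 in limma, 6 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (median -0.144, adjusted p = 0.00658, but 0.376 with an estimated correlation). Fibroblast markers had only Dcn past the threshold and 2 adjusted over the list alone (median -0.434, adjusted p = 0.00899, but 0.549 with an estimated correlation). Of the 14 list calls, 3 were lost when 1 array was left out: cytokines without medium replicate 3 (0.502), lysosome without medium replicate 2 (0.0778) and fibroblast markers without low replicate 2 (0.0799). Gene calls were lost too, without medium replicate 3 for Irf7 (0.11), Zbp1 (0.0613), Mx1 (0.094) and Dcn (0.0842), and without low replicate 1 for Mrc1 (0.125). Median, mean and test differed in sign for the nonclassical monocyte, receptor, efferocytosis, natural killer cell and T cell lists.

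In total 427 genes differed between low and medium, 307 higher in low and 120 lower, against 3121 at an unadjusted p under 0.05, and 227 differed by 2-fold or more. With quantile normalization repeated on the genes tested, 242 were higher and 162 lower, so that the share higher went from 71.9% to 59.9%. Over all genes 16.8% had groups that did not overlap, against 10% by chance. The count was 119 without medium replicate 3, 164 without medium replicate 1, 223 without medium replicate 2, 133 without low replicate 1 and 136 without low replicate 2. With the 2 gates fitted alone it was 211, and an equal-variance test per gene without moderation over genes passed 2. Of 46 named genes past the threshold, 17 kept their calls without each array in turn.

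**Figure D3:**
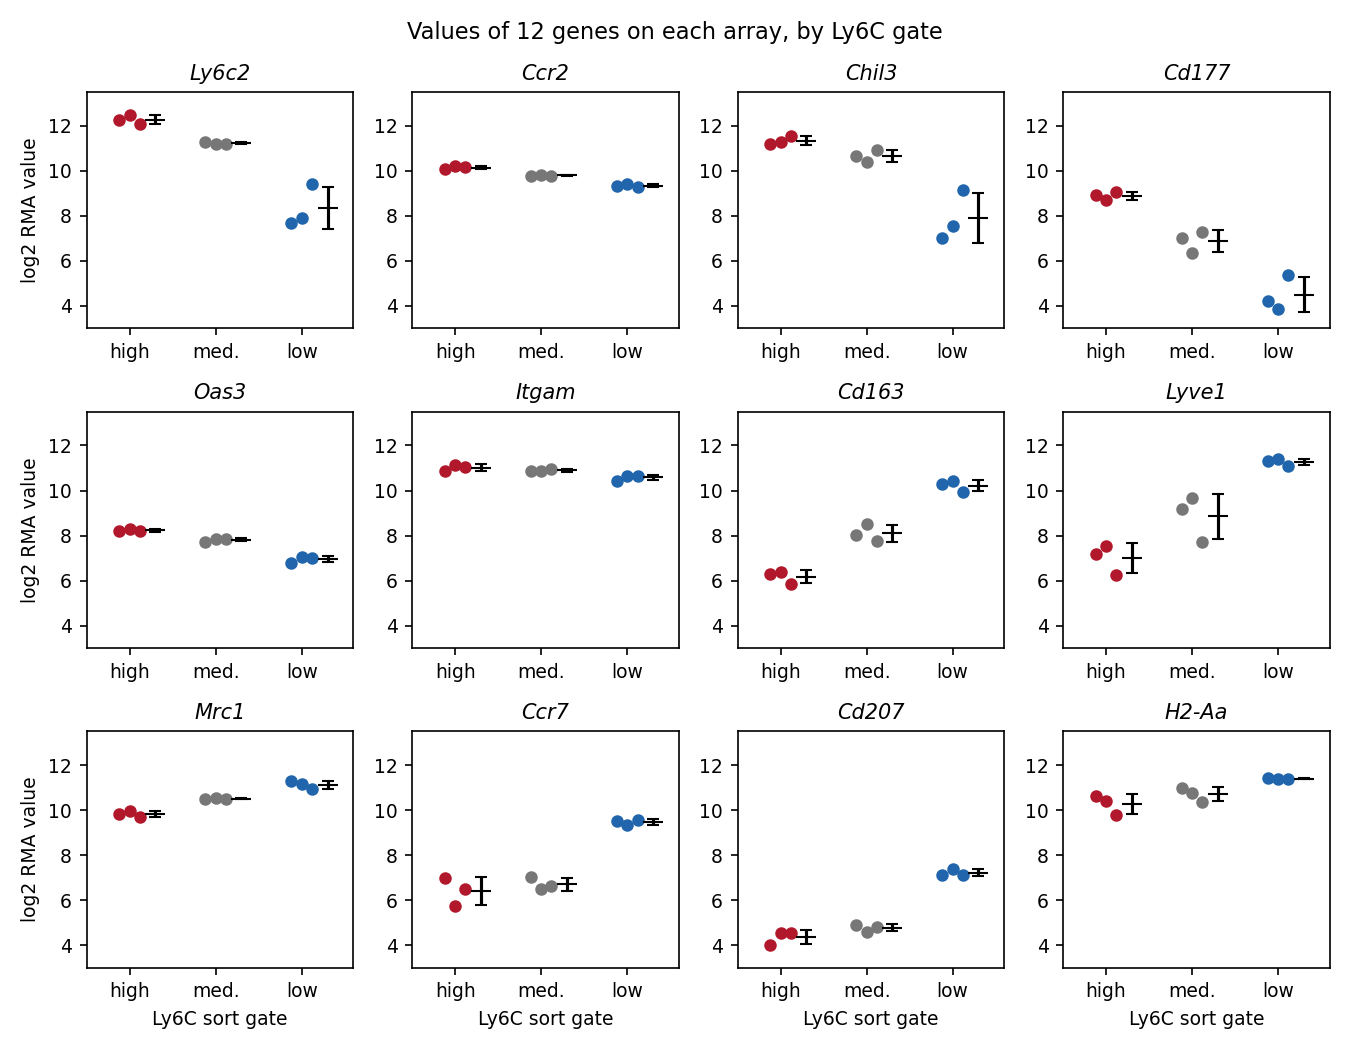
Log2 intensity (y axis) of 12 genes in the Ly6C high, medium and low gates (x axis). Points are arrays and bars show the mean and SD of 3 arrays, and Cd163 steps from 6.17 through 8.10 to 10.21 while Ccr7 stays near 6.41 and 6.72 before it reaches 9.48.

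Over the 3 gates together, 888 genes differed by the limma F test, against 3674 at an unadjusted p under 0.05. The count was 342 without low replicate 1, 343 without low replicate 2, 560 without medium replicate 1, 560 without medium replicate 3 and 585 without high replicate 2. An F test per gene without moderation over genes passed 96. The mean of medium lay between those of the other gates for 674 of the 888 genes (75.9%), and 3 genes differed from both in the same direction past the threshold. Aqp1 was lowest in medium (6.55 ± 0.44, 5.18 ± 0.02 and 9.04 ± 0.08 in high, medium and low; SD, n = 3; adjusted p = 0.029 against high). Wfdc21, a secreted protein gene (2.83, 3.88 and 2.94; adjusted p = 0.0269 against high and 0.0166 against low), and 1700048M11Rik (3.05, 3.91 and 3.23; adjusted p = 0.0449 and 0.0386) were highest in medium, both close to the floor. Wfdc21 in low versus medium and 1700048M11Rik stand outside the naming rule and were chosen after their values were seen. Such genes numbered 0 without high replicate 2 and without each medium and each low array in turn, 1 without high replicate 1 and 3 without high replicate 3. Fits of 2 gates alone and an equal-variance test per gene without moderation over genes each gave 0.

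The place of medium between high (0) and low (1) was described for the 598 genes that differed by 2-fold or more between those gates. The median was 0.316 (quartiles 0.162 and 0.494), with a standard deviation of 0.0765 over the 3 medium arrays. Genes higher in low had a median of 0.261, and genes higher in high 0.464. Of the 5 lists placed this way, fibroblast markers lay nearest to low, at 0.849 over 10 genes, and dendritic cell genes nearest to high, at 0.145 over 8 genes. Classical monocyte genes lay at 0.357 over 9 genes, tissue macrophage genes at 0.341 over 16 genes and interferon response genes at 0.277 over 8 genes. The standard deviation over the 3 medium arrays was 0.172 for tissue macrophage genes, against 0.0132 to 0.0662 for the other lists. These places were not tested, since the high and low values choose the genes.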

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

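Leaving out the genes that follow the fibroblast markers was chosen only after the results were seen; the other alternatives were planned. No result reversed under any alternative. Except where given here, counts of genes stayed within 1.5 times their value. Fitting only the 2 gates compared gave 644 genes for low versus high, 1 for medium versus high and 211 for low versus medium, with 0 for medium outside both gates, where fewer residual degrees of freedom are left; the F test has no such fit. An equal-variance test per gene gave 6, 0 (1126 unadjusted) and 2 genes, 96 by the F test and 0 for medium outside. It drops the moderation of variances over genes, and the cause was not tested. A 2-fold threshold, which only removes genes, gave 598 for low versus high and 227 for low versus medium. Without the 127 genes that correlate at 0.9 or more with the fibroblast list, medium versus high had 0 genes in limma (1554 unadjusted) and medium outside 0, partly by construction and with the log2 differences of the genes still tested kept, while low versus high had 1078. Medium outside was 1 gene among the 11540 genes above the array median, 1 among the 6306 at a log2 value of 6 or more, and 5 with the replicate block; the cause was not tested. Lists for medium versus high were 6 with the filter at 6 (the cause was not tested), 3 with an estimated correlation and 3 with fry. Lists were 6 for low versus high and 4 for low versus medium with an estimated correlation; the cause was not tested. Fry called 9 for low versus medium, and its test for change in either direction 26 for low versus high and 25 for low versus medium; it compares no list with other genes. Leaving out each array in turn gave 596 to 1243 genes for low versus high, 2 to 72 for medium versus high, 119 to 522 for low versus medium, 342 to 827 by the F test and 0 to 3 for medium outside. Lists were then 13 to 14, 9 to 15 and 12 to 14, and the median position 0.259 to 0.364. The labels do not say that the replicate numbers pair the samples, and the deviations of same-number arrays from their gate means correlated over 0.1 in only 4 of 9 pairs (-0.0166 to 0.309). The 3 pairs of replicate 3 were among these (0.106 to 0.309), and 5 of 9 arrays correlated best with an array of their own number, a hint from the data and not from the design. As a fixed block they gave 1564, 61 and 629 genes, sharing 1142, 43 and 381 with the fit without a block, and as a random block the correlation was 3.08e-05. With the fixed block, Il1b, Ly6C low versus high, passed (adjusted p = 0.0424, range 0.0424 to 0.506 over the alternatives), as did Ptgs2 (0.0108, range 0.0102 to 0.414) and S100a8 (0.0409, range 0.0409 to 0.861). For low versus medium it added Ptgs2 (0.0283, range 0.0248 to 0.552) and Arg1 (0.0438, range 0.0201 to 0.418). It also called the nonclassical monocyte list for low versus high (0.0412, range 0.0412 to 0.654) and the inflammatory cytokine list for medium versus high (0.0296, range 0.00337 to 0.968). Over the planned and added alternatives other than left-out arrays, 223 tests of named genes lost their call, 15 gained one and 1993 kept their side of the threshold. For lists the numbers were 59, 12 and 1125. A further 2 tests of genes and 52 of lists changed direction without passing the threshold either way. With each array left out in turn, 338 tests of named genes lost their call, 6 gained one and 1353 kept their side of the threshold. For lists these numbers were 11, 9 and 777, and 22 tests of genes and 40 of lists changed direction without passing. Repeated quantile normalization ended the calls of H2-Oa, Top2a and Ier3 in low versus high. Signal over background limits the dimmest genes.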

Other observations

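The tests of gene families, of whole-tissue debris, of natural killer and of dendritic cells were chosen only after the results were seen. Genes were grouped into 591 families by the stem of their symbols. Of 8 Schlafen genes, regulators of proliferation and viral replication in immune cells, 3 were lower in Ly6C low than in high: Slfn1 differed by -2.56 (limma adjusted p = 0.00142), Slfn4 by -1.84 (adjusted p = 0.00675) and Slfn5 by -0.73 (adjusted p = 0.023). The family had a median of -0.974 (camera adjusted p = 0.000591, but 0.753 with an estimated correlation). In all, 22 families were called, 15 higher in low and 7 lower, and those given here are examples picked after their values were seen. The share of members that passed on their own differed between families. Mitochondrial ribosomal genes had 1 of 28 Mrps genes higher (median 0.469, adjusted p = 2.97e-05) and 3 of 43 Mrpl genes (0.401, adjusted p = 0.000418). The chaperonin genes Cct had 2 of 9 higher (0.331, adjusted p = 0.00124), Washc genes of the endosomal WASH complex 3 of 5 (0.544, adjusted p = 0.000591) and the helicase genes Mcm 2 of 10 (0.868, adjusted p = 0.00133). The others called higher included Idh, Exosc, Utp, Alg, Timm and Nup. None of the families named here, with or without a value, was called with an estimated correlation (camera adjusted p = 0.753 for each).

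Fibroblast genes were higher in Ly6C high than in low, 10 of 11 past the threshold. Tests of a second fibroblast list and of mesenchymal regulators, written before those genes were seen, and of other tissues weighed 3 explanations. None of the 11 fibroblast genes is in another list, and 2 were at a log2 value of 6 or more in Ly6C low; the CD11b gate would remove fibroblasts. Debris of the whole wound is argued against, since the highest median of endothelial, keratinocyte and muscle markers, high minus low, was 0.353 against 3 for fibroblasts. Fibroblasts or their RNA in the Ly6C high sort may be a source: the second list had a median of 1.02 with 13 of 29 genes past the threshold, between what that source and its absence would give. For matrix genes alone switched on in the myeloid cells, mesenchymal regulators had a median of 0.393 with 0 of 14 genes past limma's threshold. Of these, 8 were higher in high at an unadjusted p under 0.05. They were dim even in high (Meox2 5.5, Prrx1 5.05), so their median cannot decide. The surface protein genes Thy1 (2.18, limma adjusted p = 0.0176) and Cd248 (2.41, 0.0344) were higher in high, which matrix genes alone would not give. Ddr2 and Scara5 were not past the threshold (0.0939 and 0.458). These genes were chosen after their values were seen.

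Klrd1 and Klrb1b, natural killer cell receptor genes, were higher in Ly6C low; Klrb1b went from 5.84 to 9.51 (log2 difference 3.67, adjusted p = 0.000178) and was chosen after its values were seen. Natural killer cells can carry CD11b, so the gate would not remove them all. Their presence is argued against: the list's 10 markers, none of them in another list and 0 at 6 or more in Ly6C high, had a median of -0.0392 and an upper quartile of 0.143, against 3.15 for Klrd1, and Gzma (2.94) and Nkg7 (4.24) were dim in low. Klrk1 alone of the other markers went with natural killer cells, 1.92-fold higher in low (5.91 to 6.85, adjusted p = 0.00912). Dendritic cells in the low gate may be a source. Their list was higher there (camera adjusted p = 0.0071 with an estimated correlation), although 6 of its 23 genes are in other lists. That value was known before this explanation was weighed. It does not bear on which cells hold Klrd1 and Klrb1b, so it cannot decide. Expression of these receptors by the macrophages themselves was not tested and stays open.

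Ly6C medium lay between the other gates, and a mixture of high and low cells could place it there. Such a mixture needs the same share of low cells from every gene on the linear scale. The 111 bright genes higher in low needed a share of 0.158 and the 111 higher in high 0.455. Their difference of 0.297 (0.285 to 0.341 when each array was left out) argues against a mixture as the whole cause, and it was 0.271 without the genes that follow the fibroblast markers. A mixture stays open, as does a distinct or intermediate state of the medium cells, which was not tested.

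Other splits of the samples were counted. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, was as large in each comparison: 1258, 53 and 427 genes, with 0 as the highest of the others each time, and 13, 12 and 14 lists, with 12, 10 and 11 as the highest of the others. For the F test, 1 of 100 splits, the real one, gave 888 genes, and the highest other gave 641. The splits beside the real one were a random draw of those possible. For the genes of the F test, chance in the assignment of these arrays to gates is argued against. For the numbers of lists it is not, since other splits gave nearly as many. As the replicates may be technical, chance differences between animals or sorts are not covered. For the 3 genes with medium outside both gates chance cannot be excluded, since 5 of 100 splits gave as many, and the highest other gave 349. In the 4 other splits a whole gate took the place of medium, Ly6C low in 3 and Ly6C high in 1. The structure behind their counts is therefore the gates themselves, and these splits decide little about chance.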
